A study of Mus musculus with 10 samples.

How the data were processed

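RNA from the livers of 10 male mice was measured on one-colour Agilent arrays, 1 array per mouse, with 5 control and 5 hyperlipidemic samples as the group label gives them. Per the labels' protocols, RNA was amplified and labelled with Cy3. The same protocols describe a blood RNA kit with red cell lysis and globin removal, and the molecule field names DNA, while the source, description and growth fields name liver or whole mice. The samples are treated as liver RNA, as labelled, and this conflict was not resolved by the labels. Replicate numbers follow accession order and pair nothing.

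Per the file headers, spot intensity was extracted by the authors with Agilent Feature Extraction, which subtracted background and detrended each array to give a processed signal. The header names the mm9 build. No normalization between arrays had been applied to these values. Flags for spots well above background and for outliers come from the same files. The authors' deposited value table holds log2 values. Set against the scanner files, each column equalled the mean log2 processed signal per probe plus a constant for that array (SD of the difference 0.00). That constant put the column's 75th percentile over probes at 0.00, so its scale and direction are known and it is not centred per gene. The values analysed here use a percentile over spots, so the constants differ, at -6.18 in the value table and -6.38 here for control replicate 1. Its column medians were -2.70, -2.80, -2.73, -2.33 and -2.81 for control replicates 1 to 5 and -2.71, -2.81, -2.83, -2.77 and -2.69 for hyperlipidemic replicates 1 to 5. How the value table was made is not given in the sources used here.

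Each array held 180880 spots, of which 175906 were no controls. Control spots and outlier-flagged spots (3 to 3945 per array) were left out, no spot was saturated (0 on each array), and spots of a probe were averaged on the log2 scale. Of the probes, 96123 had an unflagged spot on every array and 1713 were lost. Values are log2 of the processed signal minus each array's 75th percentile over its non-control spots. Kept features were well above background on at least 4 of 5 arrays of at least 1 group. Probes of 1 gene matched by RefSeq accession were represented by the probe with the highest mean over the 10 arrays, while RIKEN clones stayed separate features, which left 30244 features. Groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all features and a threshold of 0.05. Intervals are 95% intervals from the same fit. Log2 values are differences, and no probe's level is set against another's.

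The array files pair probes with no gene names. Of the 96123 probes, 37678 were catalogue probes with Agilent identifiers, which have no gene in the tables used here, and 58445 were named after a transcript. Unversioned RefSeq accessions were matched to a RefSeq gene table of assembly GRCm38.p6, which named 838 of 869 NR probes and 3810 of 12122 XR probes. Clone names were matched to its symbols and synonyms, which named 1199 of 15623 RIKEN probes. NONCODE, Ensembl and ultraconserved probes stayed unnamed. As that assembly is not the build of the headers, it gave names, gene classes and neighbours only. Of the tested features 961 had a gene, 693 of class long non-coding RNA and 211 protein-coding. No file gives a class for the other probes, so these were counted together, as planned for that case. The level of Apoe and the genes of the catalogue probes were not analysed here, and 26 of the 34 gene lists had no named feature tested. Of the 7 lists with a single tested member, 1 is not reported here.

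The text names features by a rule set before the data were examined: Apoe, the 12 messenger RNAs and 5 long non-coding RNAs with the largest change in each direction among those past the threshold with separate groups and signal on all arrays of the higher group, up to 4 members of each list past the threshold, and the 2 members of a list with the highest mean signal where fewer than 2 passed. A set of always-named liver genes was part of the rule too, and none of these was among the named features tested. The Zfp235 clone, 8 of the 10 established long non-coding RNAs, the transcripts of liver genes and the transcripts beside lipid genes were added after values were seen. At most 2 unnamed probes per direction are printed. Gene lists with at least 3 tested members were tested with camera at a preset correlation of 0.01, and 1 list qualified. Camera with an estimated correlation and fry were alternatives.

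On simulated arrays with the means and SDs of the 30244 features, the same functions recovered 27 of 100 features changed 2-fold and 90 of 100 changed 4-fold in the comparison of hyperlipidemic with control, with 4 false calls. Values were drawn independently for each feature and array, with no slide or labelling effect. These rates therefore need not hold for the real arrays. Duplicate spots of a probe differed by an SD of 0.14 to 0.18 log2 within an array. Arrays of one group differed by an SD of 0.35 to 0.86 across features (20 pairs, r of 0.924 to 0.988), so no 2 arrays were copies of each other. Arrays of different groups differed by 0.46 to 1.05 (25 pairs), which overlaps the range within groups.

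Alternatives fixed beforehand were quantile normalization, a 75th percentile over probes well above background on all arrays, normexp background correction with an offset of 50, the authors' value table, no filter, a filter on all 10 arrays, slide as a fixed or random block, the slide with both groups alone, the mean of a gene's probes, array weights, a trended robust prior, 2-fold thresholds, adjustment within classes and leaving out each array. For normexp the planned mean signal is not among the columns used here, and the median signal took its place with the median background. Alternatives added after seeing the data were the spike-in sets as a block, the spike-in set with both groups alone, leaving out control replicate 4 and hyperlipidemic replicate 4 together, and the groups of transcripts described last. Figures were drawn with matplotlib 3.10.9.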

Results

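Livers of 10 male mice were each profiled on 1 one-colour expression array, with 5 wild-type control mice on regular food and 5 hyperlipidemic mice. The hyperlipidemic mice lacked apolipoprotein E, the lipoprotein component that lets the liver take up remnant particles, and ate a high-fat food with 2.5% cholesterol and 15% fat. Genotype and food changed together, so the comparison measures both at once. All mice carried the C57BL/6J strain name and an age of 42 days. The comparison asked which long non-coding RNAs and messenger RNAs differed between the livers of hyperlipidemic and control mice. Probes for coding and non-coding transcripts shared each array. Per array, 33.6% to 49.2% of 175906 non-control spots were well above background, and the number of arrays limits the precision of a group mean. Nothing in the labels says more about how the samples of a group were taken, so p-values measure the spread between these samples.

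Few transcripts separated the 2 groups. Of 30244 features tested, 13 rose and 8 fell in hyperlipidemic livers at a limma adjusted p under 0.05. For all 21, every hyperlipidemic array lay beyond every control array. The catalogue probes, which carry no gene name in the tables used here, held 8 of the features that rose and 6 of those that fell. These changes therefore carry no gene name here, and the level of Apoe itself was not analysed here. Probe A_55_P2076891 fell by 5.05 on the log2 scale (SE 0.21, adjusted p = 2.08e-08), from 4.18 ± 0.35 to -0.87 ± 0.25 (SD, n = 5 per group) relative to the array's 75th percentile. Probe A_51_P171999 fell by 4.72 (SE 0.21, adjusted p = 2.08e-08) and stayed well above background on all 10 arrays. Probe A_51_P281778 rose by 4.63 (SE 0.38, adjusted p = 4.38e-05) and was well above background on 2 of 5 control arrays and 5 of 5 hyperlipidemic ones. Probe A_55_P2288983 rose by 3.04 (SE 0.24, adjusted p = 3.66e-05), with 1 of 5 control arrays well above background. With control signal raised to each array's lowest signal that counted as well above background, these rises were 3.91 and 2.62. With slide as a block, which rests on 1 control array, probes A_55_P2076891 and A_51_P171999 differed by -5.34 and -4.76 and still passed. Probes A_51_P281778 and A_55_P2288983 then differed by 3.91 and 2.91 and did not pass.

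**Figure D1:**
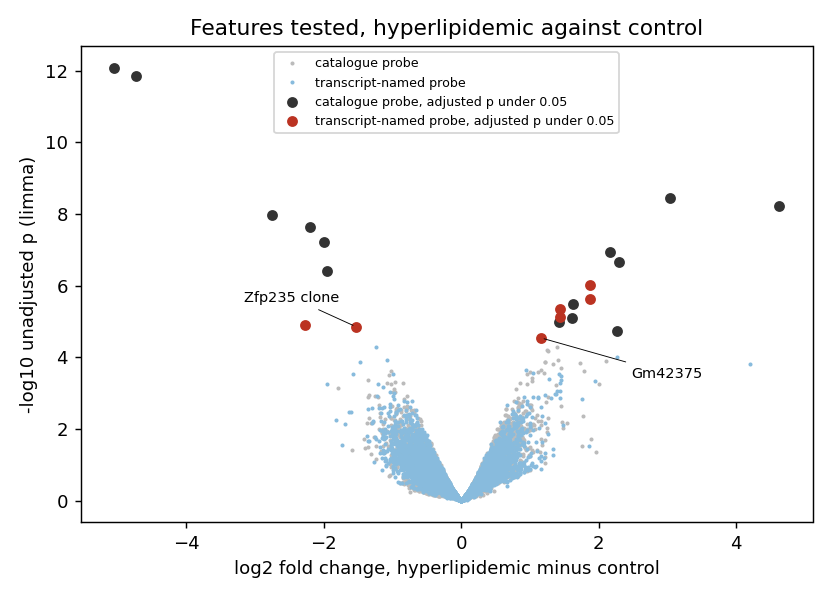
Log2 fold change (hyperlipidemic minus control, x axis) against -log10 of the unadjusted limma p (y axis) for 30244 features, each point being 1 feature, with catalogue probes in grey or black and transcript-named probes in blue or red. Larger points passed an adjusted p under 0.05, 13 to the right and 8 to the left, and the 2 of them with a gene name are marked.

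Among the 11106 transcript-named features, named after NONCODE, RefSeq, RIKEN or other transcripts, 5 rose and 2 fell. Those that rose were 4 NONCODE transcripts without a gene name here, at log2 changes of 1.43 to 1.88, and Gm42375, a predicted long non-coding RNA. Both that fell were probes of RIKEN cDNA clones. The first of these clones matched no gene and the other bears a synonym of Zfp235, a zinc finger gene. Counted by the gene class of the reference table, which gives none for NONCODE transcripts, 1 of 693 tested long non-coding RNAs rose and 0 fell. Of 211 features matched to protein-coding genes, 0 rose and 1 fell. At an unadjusted p under 0.05, limma gave 19 long non-coding RNAs higher and 23 lower, and 2 protein-coding matches higher and 16 lower. Of the 211 protein-coding matches 198 are RIKEN clones, and all 3017 RIKEN features leaned the same way at that level, with 53 higher and 167 lower, against 589 higher and 359 lower for catalogue probes. Over all features 1757 passed that unadjusted level, where 1512 would by chance. Groups did not overlap in 0.972% of all features, and chance gives 0.794%.

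Gm42375 overlaps Cyp2a4, a cytochrome P450 that hydroxylates steroids and is more active in female liver. Its log2 level rose by 1.16 (SE 0.19, adjusted p = 0.0410), from -1.34 ± 0.25 to -0.19 ± 0.18 (SD, n = 5 per group), which is 2.23-fold. It was well above background on 3 of 5 control arrays and 5 of 5 hyperlipidemic arrays. The probe of the Zfp235 clone fell from -0.92 ± 0.41 to -2.45 ± 0.32 (SD, n = 5 per group), with an adjusted p = 0.0224. It was well above background on 5 of 5 control arrays and 0 of 5 hyperlipidemic arrays, so the decrease is a bound, at least 1.53-fold for the means of the processed signal. Such a bound sets the dimmer group at the lowest signal that counted as well above background on each array, where that is higher. It does not allow for the spread between arrays or for another background correction. A clone name listed as a synonym may report another transcript of the locus than the messenger RNA. With slide as a block, which rests on the single slide that held both groups (1 control and 3 hyperlipidemic arrays), neither passed (adjusted p = 0.9999 and 0.279). The fitted difference of Gm42375 was then 1.25 (SE 0.35, against 0.19 without the block) and that of the Zfp235 clone, whose hyperlipidemic signal was not well above background, -2.23 (SE 0.38) against -1.52 (SE 0.24), so the differences did not shrink and the SE rose. With normexp, which adds an offset of 50, they were 0.48 and -0.42 (limma adjusted p = 0.25 and 0.58), so the size of both depends on the processing. The -0.42 is smaller than the bound above, which is -0.62 on the log2 scale. This setting changes signal column, background correction and offset together, and their parts were not tested apart. Gm42375 also missed the threshold without control replicate 1, 2, 4 or 5 or hyperlipidemic replicate 1, 2, 4 or 5 (adjusted p of 0.0863 to 0.201), with a difference of 1.1 to 1.26 whichever array was left out. The Zfp235 clone missed it without control replicate 2, 3 or 5 or hyperlipidemic replicate 1, 2, 3 or 4 (0.0512 to 0.0951), with a fitted difference of -1.64 to -1.37 whichever array was left out.

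**Figure D2:**
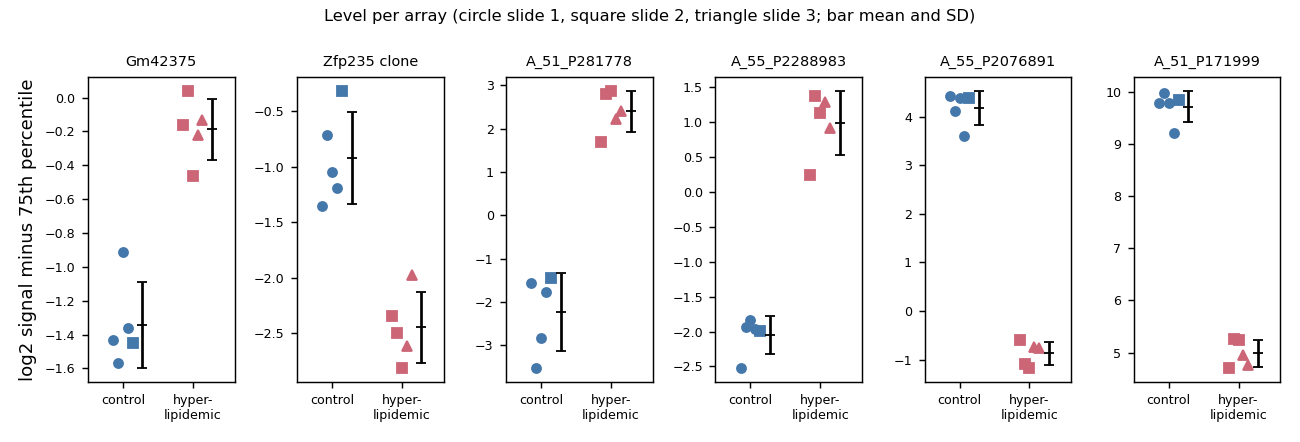
Normalized log2 signal per array (y axis, log2 signal minus the array's 75th percentile) of Gm42375, the Zfp235 clone and 4 catalogue probes in control and hyperlipidemic livers, each point being 1 array (circle slide 1, square slide 2, triangle slide 3) and the bar the mean ± SD of n = 5. In each panel the groups do not overlap, and Gm42375 moves from -1.34 to -0.19.

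Those long non-coding RNAs with established names that were tested did not pass. The list fixed beforehand held 47 symbols, counting alternative names of a gene, and 10 members were tested. Other members, such as Neat1 and Malat1, were not among the named features tested. Of the 10, 0 rose and 0 fell, over all features or adjusted over the list alone. Norad, an abundant RNA that binds Pumilio proteins, differed by -0.28 (95% interval -0.74 to 0.19), and Snhg8, a host of small nucleolar RNAs, by -0.35 (-0.90 to 0.21). The widest differences were -0.60 for Snhg3, another small nucleolar RNA host, -0.47 for Dleu2, a microRNA host, and 0.45 for the imprinted Peg13, with adjusted p = 0.827 for each. When 1 array was left out they ran from -0.75 to -0.33, from -0.64 to -0.38 and from 0.30 to 0.64. With the spike-in sets as a block they were -0.25, -0.19 and 0.31. Trp53cor1 and Lncpint, both known to respond to p53, differed by -0.18 and 0.06, Mir22hg by -0.13 and Gm15441, which overlaps Txnip, by 0.25. Snhg5 differed by -0.27, and by -0.42 to -0.03 when 1 array was left out. As a set the list had a median of -0.22, with 7 of 10 members below 0 and a camera adjusted p = 0.0642, which equals the unadjusted p because 1 list was tested, or adjusted p = 0.320 with an estimated correlation. In 13 of 25 alternative settings it passed 0.05, among them slide as a block (adjusted p = 0.0281, with a median of -0.46) and the slide of both groups alone (adjusted p = 0.0176). It also passed without control replicate 1 (adjusted p = 0.0360) or 4 (adjusted p = 0.0185), or without hyperlipidemic replicate 2 (adjusted p = 0.0479) or 5 (adjusted p = 0.0350). It moved away from the threshold with the spike-in sets as a block (adjusted p = 0.333, with a median of -0.16) and within the set of both groups (adjusted p = 0.434). The same held without control replicate 2 (adjusted p = 0.224, with a median of -0.14) or 5 (adjusted p = 0.141), or without hyperlipidemic replicate 1 (adjusted p = 0.232) or 4 (adjusted p = 0.158, with a median of -0.12).

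**Figure D3:**
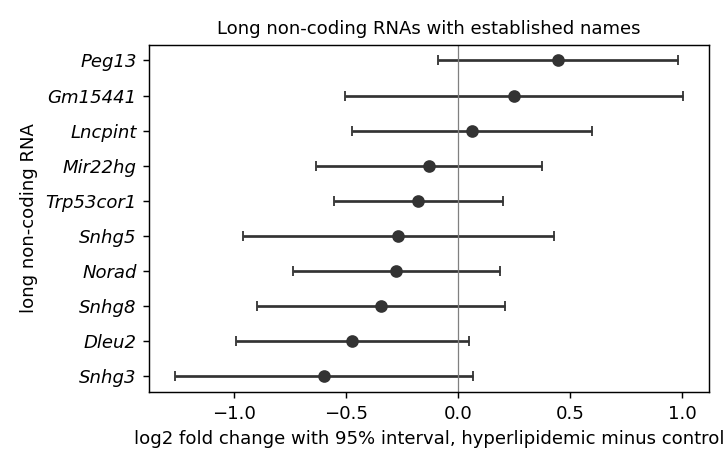
Log2 fold change (x axis, hyperlipidemic minus control) with its 95% interval for the 10 established long non-coding RNAs tested (y axis), each point being the limma estimate from n = 5 arrays per group. All 10 intervals include 0, and the estimates run from -0.60 for Snhg3 to 0.45 for Peg13.

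Of 34 gene lists fixed beforehand on lipid, bile acid, inflammatory, hepatocyte and other cell-type genes, 7 more had a single tested member each, always as a RIKEN clone, and 26 had none. Of the 6 described here, 0 passed the test over all features. The clone of Fads2, a fatty acid desaturase, differed by -0.09 (SE 0.34, adjusted p = 0.960). The clone of Cxcl14, a chemokine, differed by 0.32 and that of Igf1, the growth factor, by -0.03. The clock gene clone Cry2 differed by -0.20. The clones of Sod1, the cytosolic superoxide dismutase, and Rgs5, a pericyte marker, had intervals just below 0, with -0.43 (-0.86 to -0.01) and -0.74 (-1.43 to -0.04), and an adjusted p = 0.827 for both. Adjusted over the list alone, where a list of 1 member equals the unadjusted p, 2 of the 6 passed, Sod1 at 0.0453 and Rgs5 at 0.0391, while the exact permutation p was 0.0238 and 0.0714. With slide as a block they differed by -0.63 and -0.94, and neither passed. The Igf1, Cry2, Cxcl14 and Fads2 clones then differed by -0.98, -0.69, 0.39 and -0.18. These values rest on control replicate 5, the only control array on the slide that held both groups. Without hyperlipidemic replicate 4 the Rgs5 clone differed by -0.44, and with the spike-in sets as a block the Sod1 and Rgs5 clones differed by -0.23 and -0.41.

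Transcripts of liver genes were chosen after their values were seen, to describe the tissue. Cyp2d13 and Cyp2d37-ps, which belong to the hepatic Cyp2d family, Hnf4aos, on the opposite strand of the hepatocyte regulator Hnf4a, and Adh6-ps1 were well above background on 5 of 5 arrays of both groups. Their differences were 0.12, -0.33, 0.08 and 0.23, and none passed. A RIKEN clone of Hnf4aos gave 0.17. Serpina4-ps1 varied within both groups, at -1.78 ± 1.92 in control and 0.08 ± 1.20 in hyperlipidemic livers (SD, n = 5 per group), and its difference of 1.86 had an adjusted p = 0.827. It was well above background on 2 of 5 control and 4 of 5 hyperlipidemic arrays, and the difference was 1.31 with control signal raised to the lowest that counted as such. That difference was -0.03 with slide as a block, 2.94 with the spike-in sets as a block, and 1.13 (without control replicate 4) to 2.44 (without control replicate 5) when 1 array was left out. Of 23 alternatives it passed only within the spike-in set that holds both groups, also at 2.94, which rests on control replicate 4 at -4.70, where the lowest signal well above background was -2.42. Transcripts beside lipid genes differed little. Gm30843 beside the bile acid transporter Slco1a1 gave -0.04, Gm10768 beside the exporter Abcc2 gave -0.06, and 1300002E11Rik beside Ehhadh, an enzyme of peroxisomal fatty acid oxidation, gave 0.03 from its RefSeq probe and 0.11 from its clone.

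Slide and labelling differed between the groups. Slide 1 held control replicates 1 to 4, slide 2 control replicate 5 with hyperlipidemic replicates 1 to 3, and slide 3 hyperlipidemic replicates 4 and 5. With slide as a block, limma called 0 features higher and 3 lower (480 at an unadjusted p under 0.05), and within slide 2 alone 0 higher and 2 lower (542 unadjusted). Both fits give the same fitted differences, because slides 1 and 3 held 1 group each. All 21 features kept their direction there. As their groups did not overlap, no other outcome was possible. The arrays fell into 3 sets by the ratio of a pair of spike-in RNAs added at labelling. Another of these, E1A_r60_1, was brightest in control replicates 1 to 3, at a processed signal of 15808 to 18774, against 3143 to 3710 in control replicates 4 and 5 and hyperlipidemic replicates 1 and 2, and 5659 to 7722 in hyperlipidemic replicates 3 to 5. With these 3 sets as a block, 6 features were called higher and 3 lower. Within the set holding 2 arrays of each group, 28 were called higher and 5 lower. Only 11 of these calls were among the 21 features, and 1 of the 2 control arrays there was control replicate 4. Control replicate 4 had the most spots well above background and lay farthest out on the main axis of variation, which held 35.9% of the variance and did not separate the groups. Without it, 9 features were called higher and 7 lower. Without control replicate 1 or hyperlipidemic replicate 2, 8 were called higher.

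**Figure D4:**
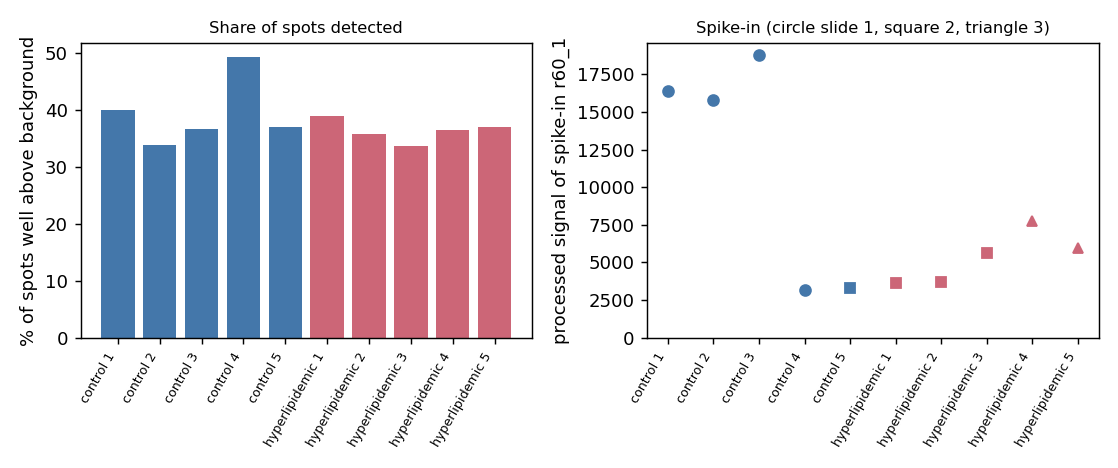
Percent of spots well above background per array (left, bars) and processed signal of 1 spike-in RNA per array (right, points, circle slide 1, square slide 2, triangle slide 3), with control arrays in blue and hyperlipidemic arrays in red. Control replicate 4 stands at 49.2% of spots, and the spike-in signal is 15808 or more in control replicates 1 to 3 and 7722 or less in all other arrays.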

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

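All tests in this part follow a fixed rule for a single array that lies far from the other 4 of its group. Chance flags about 1 in 20 group values, and 3 of 78 group values were flagged, where 3.9 would be by chance. Snhg5 in hyperlipidemic replicate 4 stood at a normalized log2 level of 0.030, while the other hyperlipidemic arrays lay between 1.15 and 1.32. The Fads2 clone in control replicate 4 stood at 4.56, while the other control arrays lay between 5.98 and 6.12. The Igf1 clone in control replicate 5 stood at 2.58, while the other control arrays lay between 0.81 and 1.28.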

How the results depend on the processing

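The counts of changed features depended on slide, labelling set and filter. The 21 features themselves kept their direction in every setting in which they were tested. Their groups did not overlap, so leaving out arrays or fitting slide or spike-in set as a fixed block could not reverse them. Settings added after seeing the data are the spike-in sets and the pair of doubted arrays. Starting from 13 higher and 8 lower, a filter on all 10 arrays gave 6 and 4, and only 10 of the 21 features could then be tested. Slide as a fixed block gave 0 and 3, the slide with both groups alone 0 and 2, the spike-in sets as a block 6 and 3, and the spike-in set with both groups alone 28 and 5. Of the calls within that spike-in set, 11 were among the 21 features. Normexp gave 5 lower. Leaving out control replicate 4 and hyperlipidemic replicate 4 gave 7 higher. At an unadjusted p with at least 2-fold the counts were 105 and 122. Leaving out each array in turn gave 8 to 18 higher and 6 to 8 lower. What caused these shifts in the counts was not tested in this part. Slide, labelling set and control replicate 4 are weighed further below for the 21 features.

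The single protein-coding match that fell (1) became 0 with quantile normalization, normexp, no filter, the filter on all arrays, slide as a fixed block, the slide with both groups alone, the robust prior, both spike-in settings and the pair of doubted arrays, and 3 at an unadjusted p with 2-fold. Of the features matched to a long non-coding RNA gene, which leaves out the 4 NONCODE transcripts that rose, 1 rose. This became 0 with the percentile over detected probes, normexp, the filter on all arrays and all 3 slide settings. It also became 0 with array weights, the robust prior, the spike-in block and the pair of doubted arrays, and 5 at an unadjusted p with 2-fold. Matched long non-coding RNAs that fell went from 0 to 1 within the spike-in set and 6 at an unadjusted p with 2-fold. Leaving out each array gave 0 to 1 for both single calls. The cause was not tested.

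The list of established long non-coding RNAs had a median below 0 in all 25 settings, from -0.46 to -0.12, with p between 0.00382 and 0.434. It passed 0.05 in 13 of them, with medians of -0.24 (quantile), -0.29 (percentile over detected probes), -0.18 (normexp), -0.18 (no filter), -0.27 (filter on all arrays), -0.46 (slide as a fixed block and the slide with both groups), -0.23 (slide as a random block) and -0.18 (without the pair of doubted arrays). These passes all use the preset correlation, and the list missed 0.05 with an estimated correlation (p = 0.320) and with fry (p = 0.377). Leaving out each array gave -0.28 to -0.12. The cause was not tested. Of 34 named features that missed the threshold, 32 missed it under all 23 alternatives run for them. Serpina4-ps1 passed within the spike-in set and the Mrpl47 clone without hyperlipidemic replicate 1. The level of Apoe, lists of fewer than 3 tested members and the rule on always-named genes were not run. No paired analysis was possible because the labels give no replicate numbers. Signal over background limits 5 of the 21 changed features, which were not well above background on any array of the dimmer group. Another 6 were so on only some arrays of that group, and 10 on all arrays of both groups.

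Named features that missed the threshold changed sign in some settings, never past the threshold (lowest adjusted p 0.846). With slide as a block, and alike on the slide with both groups alone, the values were -0.025 for Serpina4-ps1 (1.86 without a block), -0.067 for Cyp2d13, -0.20 for Hnf4aos, -0.24 for its clone and -0.39 for Lncpint. With the spike-in sets as a block, and alike within the set of both groups, they were -0.27 for Hnf4aos, -0.16 for its clone, 0.072 for Cyp2d37-ps, 0.056 for Norad, 0.033 for Snhg5, -0.14 for Lncpint and 0.15 for the Fads2 clone. Array weights gave -0.080 for Cyp2d13, -0.22 for Gm15441, 0.028 for Mir22hg, -0.027 for Lncpint and 0.18 for the Igf1 clone. Without the pair of doubted arrays the values were -0.066 for Cyp2d13, -0.024 for Hnf4aos, -0.18 for Lncpint and 0.0086 for the Igf1 clone. The percentile over detected probes gave -0.0086 for Lncpint, and normexp gave 0.027 for the Igf1 clone. Leaving out each array gave -0.084 to 0.22 for Cyp2d13, -0.080 to 0.23 for Hnf4aos, -0.028 to 0.45 for Gm15441, -0.0041 to 0.44 for Adh6-ps1, -0.085 to 0.24 for Lncpint, -0.38 to 0.052 for the Fads2 clone and -0.24 to 0.27 for the Igf1 clone. The cause was not tested.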

Other observations

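Every test in this part was chosen after the results were seen, except the splits of the arrays into other groups. Several gene-matched transcripts lay closest below the threshold and are given as values. Gm40656, beside the aldo-keto reductase Akr1c19, was lower in hyperlipidemic livers by at least 1.67-fold (adjusted p = 0.292), a bound because it was well above background on 4 of 5 control and 0 of 5 hyperlipidemic arrays. Gm38847, beside Nat8f2, differed by 1.11 (SE 0.28, adjusted p = 0.431). A clone of the pseudogene Pisd-ps3 differed by -1.08 (SE 0.21, adjusted p = 0.128), with groups that did not overlap, while its RefSeq probe differed by -0.49 (adjusted p = 0.827). Gm38426, which overlaps the kinase gene Mast1, differed by -1.12. Rnf227 and clones of Mrpl47, a mitochondrial ribosomal protein gene, Hs3st5 and Sap18 were lower and well above background on 1 of 5 hyperlipidemic arrays each. They differed by -1.35, -1.29, -0.83 and -0.76. With hyperlipidemic signal raised to each array's lowest signal that counted as well above background, these values were -0.69, -0.25, -0.82 and -0.76. A clone of Srrm4os differed by 0.76, 9030619P08Rik by 0.96, Gm8363 by -0.74 and Gm39732 by -1.04. Several shrank by more than 1.5 times within a batch, compared without raised signal. Within the slide of both groups the Srrm4os clone differed by 0.07, 9030619P08Rik by 0.32, Gm8363 by -0.49 and the Hs3st5 and Sap18 clones by -0.22 and -0.38. Within the spike-in set of both groups Gm38426 differed by -0.51 and the clones of Mrpl47, Srrm4os and Sap18 by -0.57, 0.46 and -0.39. Over the 23 alternatives Gm40656 ran from -1.42 to -0.34, Gm39732 from -1.20 to -0.35, Rnf227 from -1.82 to -0.39 and Gm38847 from 0.50 to 1.27.

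Groups of transcripts were also formed after seeing the data. Small nucleolar RNA hosts had 5 of 6 members below 0 and a median of -0.41 (camera adjusted p = 0.0581, or adjusted p = 0.503 with an estimated correlation). Clones of protein-coding genes had 121 of 198 below 0 and a median of -0.09 (camera adjusted p = 0.0172, or adjusted p = 0.503 with an estimated correlation). All 3017 RIKEN features had a median of -0.08 and catalogue probes one of 0.06, so the group lies near the median of its kind of probe and the shift is not specific to protein-coding genes. Transcribed pseudogenes had a median of 0.05 over 53 members (camera adjusted p = 0.789), opposite-strand transcripts 0.02 over 21 (adjusted p = 0.956), 3 transcripts whose symbols mark them as microRNA hosts, which leaves out Dleu2, -0.20 (adjusted p = 0.281) and 4 transcripts beside lipid genes 0.00 (adjusted p = 0.986).

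The 21 changed features exceeded what other groupings of the arrays gave. In 100 splits drawn from the 126 possible, the real one always among them, 1 gave 13 or more features in a direction and 1 gave 8 or more. That was the real split each time, and the highest of the others was 4, which argues against chance for both counts. A share of 1 in 100 is the lowest these splits can give. The real split also follows slide, so they do not tell the groups from slide. For the single long non-coding RNA match that rose and the single protein-coding match that fell, 1 of 100 splits gave as many, and the highest other was 0. The counts of 0 in the opposite directions were met by 100 of 100 splits, and the highest other was 0. Every split has at least 0 calls, so this says nothing about chance. For the established long non-coding RNAs 23 of 100 splits gave a camera p as low as 0.0642, and the lowest other was 0.000922, so chance is not excluded. A labelling batch, slide and 1 bright array were set against a difference between the groups. With the spike-in sets as a block 7 of the 21 features passed again. The other 14 kept at least 0.845 of their difference within the spike-in set of both groups (2 arrays per group, unadjusted limma p of 0.0030 or less in the fit with the block). This argues against a labelling batch as the whole cause, as far as that set can tell. Its control arrays were the bright control replicate 4, on slide 1, and control replicate 5, on slide 2 with the hyperlipidemic arrays of the set. With slide as a block 3 of the 21 passed again (adjusted p of 0.0083 or less, at least 1.01 of their full difference), which argues against slide as the whole cause of these 3, with the lone control array of slide 2 assumed to vary like the others. Without the bright control replicate 4, 16 of the 21 passed again and the other 5 kept at least 0.891, so the differences did not rest on that array alone. The groups were separate and their spread was small beside the differences. Leaving out 1 control array could therefore not remove them, and this is no independent test. The median SE rose from 0.22 to 0.36 for the 14 features that missed the threshold with the spike-in sets as a block. For the 18 that missed it with slide as a block it rose from 0.23 to 0.41. Whether the wider SE alone ended these calls was not tested. These 18 kept at least 0.721 within slide 2, but against a single control array, so slide stays open for them. The same arrays helped to select the features, which favours a high share. Genotype and food stay open as explanations too, and these data cannot separate them.

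Both gene-matched changes lie on the chromosome of Apoe, 119 protein-coding genes (Zfp235) and 189 (Gm42375) from it. Of 961 gene-matched features, 7 lay within 200 protein-coding genes of Apoe, a window set after seeing both changes so as to hold them, which makes their number there no test. A candidate explanation is DNA of the donor strain kept around the disrupted gene when the knockout was crossed into C57BL/6J. The other features of the window give little to test it on. Of these, 1 of 5 passed an unadjusted p under 0.05 (the clone of Nop53, -0.90), against 65 of 954 elsewhere (Fisher exact p = 0.300), so it stays open, as does a strain variant under a probe, which was not tested.

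The protocol names blood while the other labels name liver. Of 5 transcripts of liver genes, 4 (Cyp2d13, Cyp2d37-ps, Hnf4aos and Adh6-ps1) were well above background on all 10 arrays, but they were chosen with their signal known, so this does not tell the sources apart. No red or white cell marker was among the named features tested, and blood as the source of some or all of the RNA stays open.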
